A study of Mus musculus with 39 samples.

How the data were processed

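RNA was measured in nuclei sorted from mouse cerebral cortex, where the labels describe nuclei tagged by Nex, a transcription factor gene whose Cre driver marks the excitatory neurons of the forebrain. The series holds 39 libraries of total RNA from wild types and from mice with a conditional knockout of Kmt2c in those neurons, at 6 and 18 weeks of age and in both sexes. Per the labels' protocols, the libraries were made with the Illumina Ribo-Zero Plus total RNA kit, which removes ribosomal RNA and keeps strand.

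The deposited files hold read counts per gene, and the authors made them with featureCounts 2.0.3, per the file headers. Per the file headers, reads were counted over the whole transcript span, introns included, on an Ensembl annotation of the mouse build mm10, with a mapping quality of at least 10, strand setting 2, both ends mapped and no chimeric pairs. Reads that mapped to several places or overlapped several genes were not counted, so near-identical paralogs and overlapping genes are undercounted and their values are uncertain. The headers do not turn on the counting of read pairs, so each mate adds to a count. Per the submitters' processing notes, reads were checked with FastQC 0.11.7 and trimmed with cutadapt 5.0. The aligner is not given in the sources used here.

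Of 43432 gene IDs, 42462 were given symbols from the gene name table, and 42548 were given a biotype from GENCODE M21. Library totals, counted as reads on genes, ran from 25.21 to 53.52 M (mega-reads). Each library was assigned to its group from its title. Replicate numbers in the titles were used for naming and for the replicate block. For some libraries the files carry another replicate number than the title, so the block is uncertain for them.

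Counts were fitted with edgeR 4.0.16 under R 4.3.3: trimmed mean of M values scaling, the default filter on low counts, robust dispersions and the quasi-likelihood F test, with Benjamini-Hochberg adjustment over the 16810 genes kept and a threshold of 0.05. The model had a mean for each of the 8 groups and a term for the labelled batch within the females of each age. The batch label splits the females only. Runs were read from the output folder named in each file header, and each folder was taken as a run. Whether a folder stands for a sequencing run was not checked. Contrasts were knockout against wild type in each of the 4 combinations of age and sex, their average, the interactions of genotype with age and with sex, and 18 against 6 weeks in the wild types. All tests are two-sided, and signs are knockout minus wild type, or 18 minus 6 weeks. The labels do not say whether each library is a separate animal, so the p-values measure the spread between samples. Counts scaled to library size (CPM) use the same factors, and ± after a CPM is the SD.

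Genes are named by a rule set in advance. It takes the 10 with the largest fold change in each direction among called genes with an average log2 CPM of at least 1 and a named product. For the average it also asks for the same sign in each combination of age and sex. Of 39 gene lists written in advance, 37 had at least 5 tested members. They were tested with limma 3.58.1, using camera with a preset correlation of 0.01 between genes, with camera's estimated correlation and with fry. Camera compares a list with all other genes, whereas fry asks whether its members move on balance in one direction. An adjusted p given for a list is camera's with the preset correlation unless stated. Counts of members are given over all genes and adjusted over the list alone.

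The balance of long against short genes is the median over genes longer than 100 kb minus that over genes shorter than 20 kb, in log2 CPM centred per gene over all libraries, and was compared by exact permutation where the number of splits allowed it. The lists, contrasts, naming rule and alternatives were set before the data were examined. These alternatives were DESeq2 1.42.0, relative log expression scaling, no filter, no batch term, a block for the replicate number, 2 surrogate variables from sva 3.50.0, small and mitochondrial RNAs removed, separate fits and each library left out. Removal of a gene length trend, removal of the 6-week females of batch 1, a covariate for other cell types, splits of females with all other labels kept and splits for correlations of genes with more counts were added after the data were seen. The procedure was tested on simulated counts, and the figures were drawn with Python 3.11.15. GC content was not used here. Some genes that the naming rule takes, or that belong to the lists, are not reported here.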

Results

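The 39 libraries fall into 8 groups. At 6 weeks there were 3 wild-type and 4 knockout males, and 6 wild-type and 6 knockout females. At 18 weeks there were 4 wild-type and 4 knockout males, and 6 wild-type and 6 knockout females. Totals of reads counted on genes, in mega-reads (M), ran from 46.17 to 53.52 M in wild-type and from 37.25 to 45.41 M in knockout males at 6 weeks. In 6-week females they ran from 28.45 to 44.52 M in wild types and from 25.21 to 45.49 M in knockouts. At 18 weeks the ranges were 30.57 to 39.49 and 29.72 to 35.05 M in wild-type and knockout males, and 27.23 to 40.37 and 25.74 to 40.22 M in wild-type and knockout females. Xist, the RNA that silences the X chromosome, averaged between 939 and 1250 CPM in the female groups and at most 0.101 CPM in the male groups, as the labels of sex require. The first principal component held 29.1% of the variance, of which 96.6% lay between the 5 run folders and 0.6% between genotypes. Each run holds 1 sex, and 81.4% lay between the sexes.

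Kmt2c, the targeted gene, encodes a methyltransferase of lysine 4 on histone H3 that acts at enhancers, and its counts over the whole gene did not differ between genotypes beyond the spread between libraries. At 6 weeks males had 261 ± 5.03 CPM in wild types (n = 3) and 254 ± 3.7 CPM in knockouts (n = 4), and females had 266 ± 10.8 and 271 ± 10.2 CPM (n = 6 each). At 18 weeks males had 256 ± 9.98 and 246 ± 8.22 CPM (n = 4 each), and females 255 ± 18.4 and 250 ± 19.7 CPM (n = 6 each). The average log2 fold change was -0.03 (SE 0.02, 95% interval -0.07 to 0.02, edgeR adjusted p = 0.554). Counts over the whole gene, introns included, need not cover the deleted part, so they do not check the genotype labels. In the average edgeR called 0 of 22 listed genes of KMT2 complexes and H3K4 demethylases, over all genes or adjusted over the list alone. The list did not pass there (adjusted p = 0.846). The listed gene Kmt2d had 0.08 and 0.18 in 6- and 18-week males and -0.18 and -0.07 in 6- and 18-week females. Its interaction with sex was -0.26 (SE 0.07, edgeR unadjusted p = 0.000471, adjusted p = 0.233). Kmt2a, a methyltransferase of the same family, had an average log2 fold change of 0.01 and Pagr1a, a subunit of the KMT2C complex, -0.20 (SE 0.12, adjusted p = 0.387). Pagr1a had -0.27 in 6-week males and -0.71 in 6-week females (SE 0.23, edgeR adjusted p = 0.115). At 18 weeks it had 0.08 in males and 0.09 in females.

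The average over the 4 combinations of age and sex asks what the knockout shifts in these neurons whatever the age and sex. With 20 knockout and 19 wild-type libraries, Cpa6, a secreted carboxypeptidase, fell by 0.92 on the log2 scale (SE 0.07, 1.89-fold, adjusted p = 9.35e-13), and Oprk1, the kappa opioid receptor, rose by 0.75 (SE 0.07, 1.69-fold, adjusted p = 3.16e-10). Cpa6 went from 10.8 ± 0.0857 to 5.99 ± 0.554 CPM in 6-week males (n = 3 and 4) and from 16.1 ± 2.19 to 8.39 ± 0.969 CPM in 6-week females (n = 6 each). At 18 weeks it went from 11.5 ± 1.25 to 6.07 ± 1.6 CPM in males (n = 4 each) and from 11.7 ± 3.29 to 6.11 ± 1.85 CPM in females (n = 6 each). Evc and Evc2, neighbours whose proteins work together in Hedgehog signalling at the primary cilium, fell by 1.22 (SE 0.16, 2.33-fold, adjusted p = 6.2e-06) and 0.89 (SE 0.11, adjusted p = 6.2e-06). B3gat2, a glucuronyltransferase that helps make the HNK-1 carbohydrate, rose by 0.62 (SE 0.07, adjusted p = 7.58e-08). Olfr78, an olfactory receptor gene (-0.82, SE 0.09), the chemokine gene Cxcl12 (-0.67, SE 0.10) and the phosphodiesterase gene Pde3a (-0.66, SE 0.10) fell as well. So did Kirrel, an adhesion molecule (-0.64, SE 0.10), the sulfotransferase gene Chst9 (-0.61, SE 0.08) and the potassium channel gene Kcnk13 (-0.60, SE 0.12). The adjusted p of these 6 lay between 4.36e-08 and 0.00207.

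Ccn1, a secreted matrix protein, rose by 0.80 (SE 0.20, adjusted p = 0.0208). The early response genes Btg2 (0.58, SE 0.16, adjusted p = 0.0381) and Ier2 (0.52, SE 0.12, adjusted p = 0.00855) rose too. The nuclear receptor gene Nr2f2 rose by 0.49 (SE 0.12, adjusted p = 0.0103) and Cntnap3, a neurexin-family adhesion gene, by 0.43 (SE 0.06, adjusted p = 3.94e-06). BB557941 rose by 0.45 (SE 0.09, adjusted p = 0.00119), Nek3 by 0.53 (SE 0.14, adjusted p = 0.0268) and Vwa5a by 0.43 (SE 0.12, adjusted p = 0.0271). Most changes were small: the test called 799 genes, 299 higher and 500 lower, with a median absolute log2 fold change of 0.21 and 17 genes at 2-fold or more. The lean to lower calls depends on processing, with 320 higher and 370 lower once the gene length trend was removed and 742 and 849 with no filter on low counts. The genes called lower had a median length of 118.1 kb and those called higher 23.7 kb. Of the 799, 465 had the same sign in all 6 sets of libraries made in 1 run at 1 age and sex, against 8.4% of all genes, counted in the same libraries that gave the calls. The count was 506 without knockout 18-week male replicate 1, 494 and 493 without wild-type 6-week male replicates 1 and 3, and 1227 without wild-type 6-week female replicate 4. It was 162 without batch terms, 357 with surrogate variables and 309 without the 6-week females of batch 1, and Ccn1, Btg2, Nek3, Ier2, Nr2f2 and Vwa5a lost their calls without batch terms. With a covariate for other cell types Btg2, Nek3 and Vwa5a missed the threshold (0.58, 0.51 and 0.40; adjusted p = 0.058, 0.0591 and 0.058). The naming rule also takes Kdm5d, an H3K4 demethylase gene of the Y chromosome that was not on the list of 22, at -1.06 (SE 0.31, adjusted p = 0.0416). Its counts in females sit at the floor, and in males its log2 fold changes were -0.07 and -0.13 at 6 and 18 weeks (adjusted p = 1.0 and 0.528).

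In mm10 coordinates Cpa6 (ENSMUSG00000042501) lies on chromosome 1 from 10324720 to 10719945, Oprk1 (ENSMUSG00000025905) on chromosome 1 from 5588466 to 5606131 and B3gat2 (ENSMUSG00000026156) on chromosome 1 from 23761753 to 23849158. Evc (ENSMUSG00000029122) and Evc2 (ENSMUSG00000050248) lie side by side on chromosome 5, from 37289098 to 37336894 and from 37338499 to 37425055. Kmt2c (ENSMUSG00000038056) lies on the same chromosome, from 25271798 to 25498783. With Kmt2c, Evc and Evc2 left out, 24 of 269 tested genes within 25 Mb of Kmt2c were called in the average, 8.92%, against 4.65% on the other chromosomes and 5.21% on the rest of chromosome 5. They include Fam126a (-0.39, adjusted p = 8.16e-07), Ldb2, a cofactor of LIM-domain proteins (-0.31, adjusted p = 8.59e-06), Insig1 and Rgs12.

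**Figure D1:**
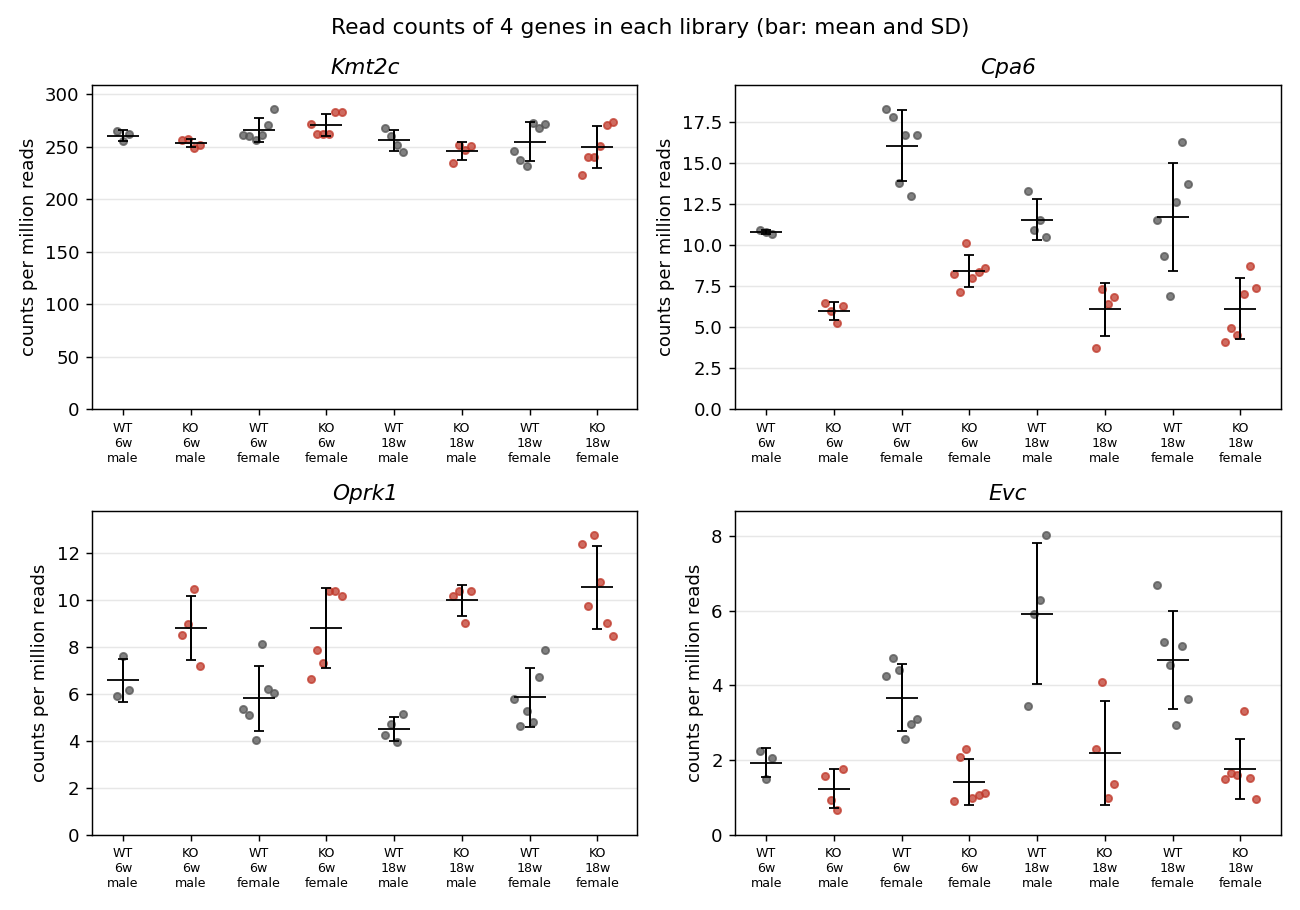
CPM (y axes, linear) of Kmt2c, Cpa6, Oprk1 and Evc in each library (points) of the 8 groups (x axis), with the group mean and SD as a line and bar. Kmt2c group means run from 246 to 271, and Cpa6 means from 10.8 to 16.1 in wild types and from 5.99 to 8.39 in knockouts.

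**Figure D2:**
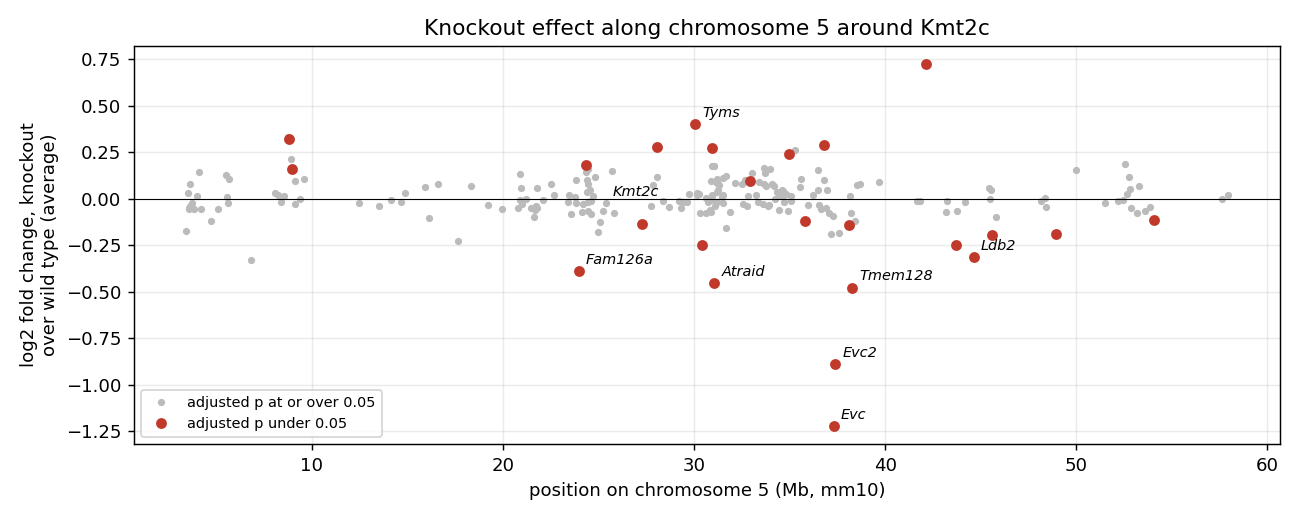
Average log2 fold change of knockout against wild type (y axis) by position on chromosome 5 around Kmt2c in Mb of mm10 (x axis), 1 point per gene with an average log2 CPM of at least 1, called genes in red. Evc has -1.22 and Evc2 -0.89, and 24 of the other 269 tested genes within 25 Mb of Kmt2c were called.

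Genes for making cholesterol and fatty acids rose together in the average. Of 24 tested, 5 rose and 0 fell over all genes, and 12 rose adjusted over the list alone (adjusted p = 1.75e-08 for the list; adjusted p = 0.28 with an estimated correlation). Among them were the cholesterol carrier gene Stard4 (0.37, SE 0.07), the sterol sensor gene Insig1 (0.28, SE 0.05) and the synthesis enzyme genes Sqle (0.21, SE 0.05) and Dhcr7 (0.14, SE 0.04). Immediate early genes, which neurons switch on within minutes of firing, rose as well: 5 of 26 over all genes and 7 adjusted over the list alone, with 0 lower (adjusted p = 1.05e-06; adjusted p = 0.563 with an estimated correlation). These were Nr4a2 (0.43, SE 0.07), Ier2, Dusp1 (0.32, SE 0.09), Btg2 and Jun (0.30, SE 0.09), while Fos had 0.26 (SE 0.11, adjusted p = 0.18). Markers of inhibitory neurons, astrocytes, oligodendrocytes and their precursors, microglia and vessels had means above 0 over the run sets, at a log2 of 0.115 (SE 0.046), 0.08 (SE 0.068), 0.098 (SE 0.075), 0.049 (SE 0.08), 0.029 (SE 0.062) and 0.208 (SE 0.124). Inhibitory neuron markers alone exceeded 2 SE, and camera called 0 of these 6 lists in the average.

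Markers of deep layer neurons moved in both directions. Of 18 layer 5 markers 5 fell and 1 rose over all genes (6 and 1 adjusted over the list alone; adjusted p = 1.92e-04; adjusted p = 0.159 with an estimated correlation). Npr3, a natriuretic peptide receptor (-0.36, SE 0.04, adjusted p = 3.42e-07), the thyroid hormone binding protein gene Crym (-0.24, SE 0.05) and the sulfatase gene Sulf2 (-0.15, SE 0.04) fell, and the transcription factor gene Etv1 rose (0.26, SE 0.07). Of 19 layer 6 and subplate markers 4 rose and 1 fell (8 and 3 adjusted over the list alone; adjusted p = 0.00972; adjusted p = 0.563 with an estimated correlation). Besides Oprk1 and Nr4a2 they include the dopamine receptor gene Drd1 (0.35, SE 0.08, adjusted p = 0.00633), and Crym, which fell, is on both lists. Drd1 had 1.00 in 18-week males but 0.04, 0.25 and 0.09 in 6-week males, 6-week females and 18-week females. Nr4a2 is also on the list of immediate early genes.

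Several synaptic and wiring groups were lower by small amounts. Of 43 axon guidance genes 6 fell over all genes (7 lower and 1 higher adjusted over the list alone; adjusted p = 0.0084; adjusted p = 0.563 with an estimated correlation). Among them were the semaphorin receptor genes Plxnc1 (-0.21, SE 0.03), Nrp1 (-0.21, SE 0.04) and Nrp2 (-0.29, SE 0.06) and the Slit receptor gene Robo1 (-0.26, SE 0.04). Of 33 glutamate receptor genes 4 fell (6 lower and 1 higher adjusted over the list alone; adjusted p = 9.09e-04; adjusted p = 0.563 with an estimated correlation), including Neto2 (-0.18, SE 0.03). Of 34 postsynaptic scaffold and kinase genes 2 fell, over all genes and adjusted over the list alone (adjusted p = 1.92e-04; adjusted p = 0.563 with an estimated correlation). They were Magi1 (-0.28, SE 0.05) and Shank2 (-0.17, SE 0.05). These 3 calls ended when a trend over gene length was taken out, with the medians going from -0.026 to 0.017, from -0.048 to -0.003 and from -0.058 to -0.008, whereas the sterol, early gene and layer calls did not. Ribosomal protein genes were higher by camera, with 2 of 75 called over all genes and 0 adjusted over the list alone (adjusted p = 0.00172; adjusted p = 0.637 with an estimated correlation). Histone genes were too, with 2 of 55 called over all genes and 2 adjusted over the list alone (adjusted p = 0.0127; adjusted p = 0.563 with an estimated correlation). For oxidative phosphorylation genes edgeR called 0 of 88, and 0 adjusted over the list alone (adjusted p = 0.0152; adjusted p = 0.637 with an estimated correlation). With a covariate for other cell types the calls of ribosomal protein, histone and oxidative phosphorylation genes ended (adjusted p = 0.161, 0.148 and 0.191), as their medians fell from 0.07 to 0.041, from 0.096 to 0.052 and from 0.037 to 0.025.

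**Figure D3:**
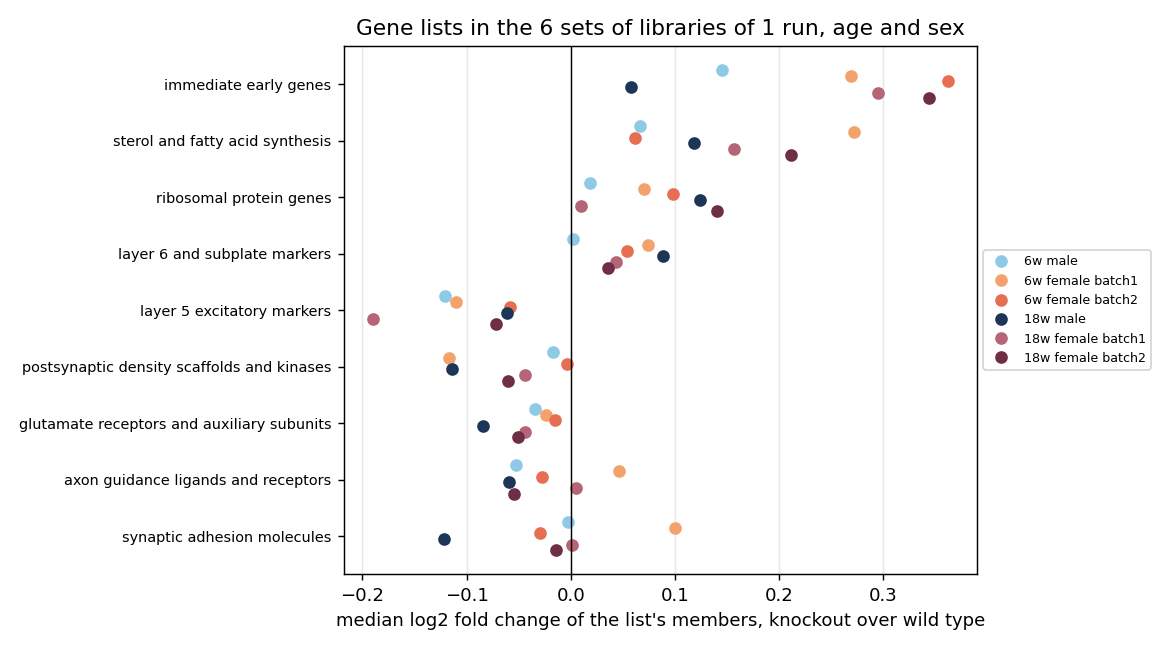
Median log2 fold change of knockout against wild type (x axis) of the members of 9 gene lists (y axis) in the 6 sets of libraries made in 1 run at 1 age and sex (coloured points). Immediate early genes and sterol synthesis genes lie above 0 in 6 of 6 sets.

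In 6-week males the comparison asks what the knockout shifts in young males. Cpa6 was the 1 gene called, and it fell by 0.85 on the log2 scale (SE 0.15, n = 3 and 4, edgeR adjusted p = 0.0264). Clock genes were higher (adjusted p = 0.0024; adjusted p = 0.078 with an estimated correlation), with 0 of 18 called over all genes and 5 higher adjusted over the list alone. Rorb, a nuclear receptor gene, had 0.50 (SE 0.15). Axon guidance genes were lower (adjusted p = 0.00855; adjusted p = 0.724 with an estimated correlation), with 0 of 43 called over all genes and 1 lower adjusted over the list alone, Nrp2 at -0.62 (SE 0.14, adjusted p = 0.269). At an unadjusted p under 0.05 edgeR gave 561 genes, and DESeq2 called 3. Leaving out any 1 of the 7 libraries gave 0 calls.

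In 6-week females, with 6 libraries of each genotype, the question is the same for young females. The primary cilium genes Evc (-1.38, SE 0.29, adjusted p = 0.0233) and Evc2 (-1.02, SE 0.20, adjusted p = 0.0154) fell. The adhesion genes Kirrel (-1.01, SE 0.17, adjusted p = 0.0027) and Cd6 (-1.0, SE 0.22, adjusted p = 0.025) and Cpa6 (-0.93, SE 0.12, adjusted p = 1.11e-05) fell too. Olfr78, Chst9, Cxcl12, the calcium release channel gene Ryr1 and Ddo, which breaks down D-aspartate, fell by 0.87, 0.85, 0.83, 0.81 and 0.78 on the log2 scale. The cholesterol carrier gene Stard4 (0.63, SE 0.13, adjusted p = 0.0154), Oprk1 (0.60, SE 0.12, adjusted p = 0.0132) and Eri1, an RNA exonuclease gene (0.53, SE 0.10, adjusted p = 0.00874), rose. The Notch target gene Hey1 (0.51, SE 0.11, adjusted p = 0.025) and the glycine receptor gene Glra2 (0.50, SE 0.09, adjusted p = 0.0052) rose as well. Eif1ax, Lin7c, Ttc9c, Lancl2 and the potassium channel gene Kcnh5 rose by 0.44, 0.40, 0.37, 0.37 and 0.35.

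Camera called 16 lists in 6-week females, and 0 of them with an estimated correlation. Immediate early genes were higher (adjusted p = 2.34e-08; adjusted p = 0.43 with an estimated correlation), with 0 of 26 called by edgeR over all genes, 4 higher adjusted over the list alone and Jun at 0.56 (SE 0.16, adjusted p = 0.0753). Their median was 0.269 in batch 1, where the medians of all 6 lists of other cell types were above 0, from 0.034 to 0.271. In batch 2 it was 0.362, and those lists ran from -0.227 to 0.153. Sterol synthesis genes were higher too (adjusted p = 1.37e-04; adjusted p = 0.43 with an estimated correlation), of which Stard4 passed over all genes and 5 were higher adjusted over the list alone. The sterol list median was 0.272 in batch 1 and 0.062 in batch 2, and Stard4 was not called with batch 2 alone. The 12 mitochondrially encoded genes had a median log2 fold change of 0.516, with 0 called by edgeR over all genes and 4 higher adjusted over the list alone (adjusted p = 0.00344; adjusted p = 0.541 with an estimated correlation). Their median was 1.065 in batch 1 and -0.05 in batch 2, so the rise is that of batch 1. The test called 74 genes, 18 higher and 56 lower. The 3 wild-type and 3 knockout libraries of batch 1 alone gave 1318 calls, 57 of them among the 74, and the 3 and 3 of batch 2 alone gave 2. Among genes above a minimum count, 75.96 to 80.08% of the counts in these batch 1 libraries were even numbers, against 58.07 to 66.63% in all other libraries. The cause was not tested. Wild-type replicates 1 and 2, both of batch 1, were closer than any other libraries of 1 group (chi-square per degree of freedom 2.9, next lowest 6.17). Whether these 2 come from separate samples was not tested, so the calls may rest on fewer samples than libraries. The count was 10, 17, 199, 271 and 284 without wild-type replicates 1, 2, 3, 4 and 6, and 26, 12, 37, 308, 30 and 148 without knockout replicates 1 to 6, so it depended on single libraries.

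In 18-week males, with 4 libraries of each genotype, the comparison turns to adult males. The growth factor gene Tgfa (1.37, SE 0.25, adjusted p = 0.00256), Oprk1 (1.15, SE 0.15, adjusted p = 1.81e-05) and the dopamine receptor gene Drd1 (1.00, SE 0.18, adjusted p = 0.00185) rose. Acot11, a thioesterase gene (1.00, SE 0.26, adjusted p = 0.0311), and B3gat2 (0.93, SE 0.15, adjusted p = 9.15e-04) rose as well. BB557941, the carbonic anhydrase gene Car2, Gpr135, Cyp2s1 and Ccdc85b rose by 0.81, 0.78, 0.78, 0.75 and 0.73. Evc (-1.42, SE 0.34, adjusted p = 0.0238), Olfr78 (-1.23, SE 0.20, adjusted p = 5.39e-04) and Armc4 (-0.99, SE 0.23, adjusted p = 0.0178) fell. So did Evc2 (-0.95, SE 0.24, adjusted p = 0.0344) and Cpa6 (-0.93, SE 0.15, adjusted p = 5.39e-04). Nxf7, Tnfaip6, Antxr2, the cadherin gene Cdh20 and Pde3a fell by 0.86, 0.85, 0.83, 0.82 and 0.80.

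Synaptic adhesion genes fell in 18-week males: 9 of 60 over all genes with 0 higher, and 25 lower and 9 higher adjusted over the list alone (adjusted p = 8.95e-05; adjusted p = 0.514 with an estimated correlation). In the same comparison the medians of all 6 lists of other cell types were above 0, from 0.088 to 0.284, as were those of heat shock genes (0.237) and mitochondrially encoded genes (0.442). Examples of adhesion genes are Cdh12 (-0.34, SE 0.08), Cadm1 (-0.34), Ntm (-0.44, SE 0.11) and Tenm2 (-0.37). Of 15 genes for GABA receptors and gephyrin 2 fell over all genes, Gabrb1 (-0.33, SE 0.07, adjusted p = 0.00885) and Gabra2 (-0.33, adjusted p = 0.0106), and 6 fell and 1 rose adjusted over the list alone. The list had an adjusted p = 0.0149, and an adjusted p = 0.416 with an estimated correlation. Layer 6 and subplate markers rose (3 of 19 over all genes, 7 higher and 1 lower adjusted over the list alone; adjusted p = 4.55e-04; adjusted p = 0.379 with an estimated correlation), through Oprk1, Drd1 and Nr4a2 (0.55, SE 0.15). The test called 402 genes, 116 higher and 286 lower, and camera called 12 lists, 0 of them with an estimated correlation. Fitted without the other groups, these 8 libraries gave 55 calls. Of 8 fits with 1 library left out, Nxf7 kept its call in 1, Gpr135, Ccdc85b, Evc2 and Pde3a in 2, and Car2, Cyp2s1 and Tnfaip6 in 3.

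The genes called in 18-week males differed in length, and the balance of long against short genes was lower in the knockouts by a difference that did not pass after adjustment. Genes called lower had a median length of 172 kb and genes called higher 17.8 kb, against 23.6 kb for all tested genes. The balance of 2507 long to 7582 short genes was 0.161 ± 0.061 in wild types and -0.084 ± 0.159 in knockouts (n = 4 each), a difference of -0.245. The exact permutation p was 0.0286, two-sided, the smallest that 70 splits allow, and 0.114 after adjustment over the 4 comparisons. In 6-week males the difference was -0.061 (exact p = 0.4), in 6-week females -0.029 (p = 0.775 by permutation; 0.002 and -0.06 within batches 1 and 2) and in 18-week females -0.038 (p = 0.82 by permutation; 0.008 and -0.084 within batches). With the trend over gene length removed 94 genes were called in 18-week males, 77 of them among the 402. The adhesion call ended (adjusted p = 0.28), and of the named genes Car2, Gpr135, Cyp2s1, Ccdc85b, Armc4, Evc2, Cdh20 and Pde3a no longer passed. Their values went to 0.69, 0.57, 0.67, 0.46, -0.85, -0.88, -0.67 and -0.65, so each kept its direction, and that of Evc2 moved by less than its SE of 0.24. The count was 70, 74, 209 and 787 without wild-type replicates 1 to 4, and 21, 209 and 730 without knockout replicates 1 to 3.

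**Figure D4:**
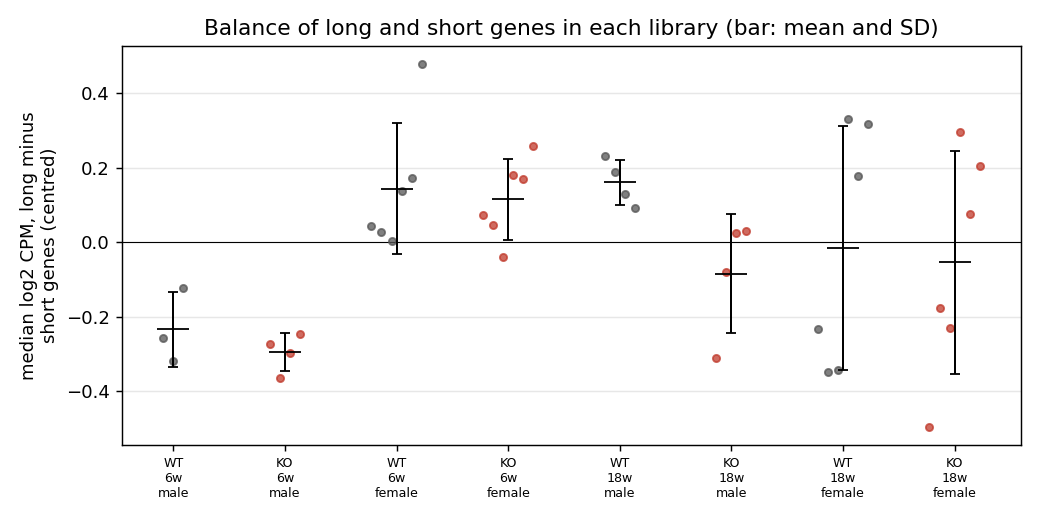
Median of genes over 100 kb minus that of genes under 20 kb, in log2 CPM centred over the libraries (y axis), in each library (points) of the 8 groups (x axis), with the group mean and SD. In 18-week males wild types have 0.161 ± 0.061 and knockouts -0.084 ± 0.159.

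In 18-week females, with 6 libraries of each genotype, the comparison turns to adult females. Ccn1 (1.64, SE 0.38, adjusted p = 0.04) and the protease gene Adamts6 (0.88, SE 0.20, adjusted p = 0.0254) rose. Oprk1 (0.86, SE 0.12, adjusted p = 4.09e-05) and the transcription factor gene Creb5 (0.80) rose as well. Crb1, Fign, BB557941, Arid5a and Zfp184 rose by 0.78, 0.77, 0.75, 0.74 and 0.70. Evc (-1.43, SE 0.28, adjusted p = 0.00987), Evc2 (-1.01, SE 0.20, adjusted p = 0.00987) and Cpa6 (-0.96, SE 0.12, adjusted p = 1.15e-05) fell. So did Kcnk13 (-0.84, SE 0.20, adjusted p = 0.0472) and the adaptor gene Blnk (-0.81, SE 0.12, adjusted p = 1.68e-04). Kif26a, Tmprss7, the peptidase gene Dpp4, the adrenergic receptor gene Adra1a and Crym fell by 0.76, 0.69, 0.63, 0.61 and 0.60.

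Layer 5 markers fell in 18-week females, and this list call held with an estimated correlation (adjusted p = 1.34e-06; adjusted p = 0.0221 with an estimated correlation). Of 18 genes 2 fell over all genes and 5 adjusted over the list alone, led by Npr3 (-0.50, SE 0.08, adjusted p = 1.68e-04) and Crym. Sterol synthesis genes were higher (adjusted p = 1.29e-10; adjusted p = 0.136 with an estimated correlation), with 0 of 24 called by edgeR over all genes and 8 higher adjusted over the list alone. Immediate early genes were higher (adjusted p = 1.91e-09; adjusted p = 0.697 with an estimated correlation), with Nr4a2 called (0.61, SE 0.12, adjusted p = 0.00987) and 9 higher adjusted over the list alone. Of the markers of other cell types, inhibitory neuron medians were 0.113 and 0.219 in batches 1 and 2 and vessel medians 0.122 and 0.309, while the other 4 lists lay on both sides of 0 or below it, from -0.246 to 0.283. Of 33 glutamate receptor genes 2 fell over all genes and 3 adjusted over the list alone, among them Gria1 (-0.34, SE 0.09). Of 34 postsynaptic scaffold genes 0 were called by edgeR, and 3 were lower and 1 higher adjusted over the list alone. Both lists were lower with an adjusted p = 0.0296, and an adjusted p = 0.786 with an estimated correlation. The test called 96 genes, 37 higher and 59 lower. Batch 1 alone gave 23 calls, 19 of them among the 96, and batch 2 alone gave 0 by edgeR, with 1314 genes at an unadjusted p under 0.05. The count was 46 without wild-type replicate 4, 63 without wild-type replicate 3 or knockout replicate 1, and 52, 44 and 158 without knockout replicates 3, 4 and 6. Of 12 fits with 1 library left out, Kcnk13 kept its call in 3, and Ccn1, Creb5, Crb1 and Tmprss7 in 4.

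Across the 4 combinations of age and sex the called genes overlapped more than independent lists would. Of the average's 799 genes 244 were called in at least 1 combination, 39 in at least 2, and Cpa6 in all 4. Lower genes shared by 6-week females and 18-week males numbered 17 (0.953 for independent lists), by 6-week and 18-week females 7 (0.197), and by 18-week males and females 21 (1.0). Higher genes shared by the same pairs numbered 2 (0.124), 2 (0.0396) and 8 (0.255), and 1 gene moved in opposite directions in 6-week females and 18-week males. These comparisons share no libraries, but they share a fit and its estimate of spread per gene. The overlaps were not compared with permuted splits. Spearman correlations of fold changes across genes, which are not independent replicates, ran from 0.099 between males and females at 18 weeks to 0.2 between 6-week males and 18-week females. Permuted genotype splits gave a correlation as large in size in 2 of 100 for the latter pair and in 6 to 44 of 100 for the others, so most of these correlations did not stand apart from chance. Among genes with an average log2 CPM of at least 3 they ran from 0.139 to 0.393, and the same splits gave one as large in 4 of 100 for 6-week males with 18-week females and in 15 to 58 of 100 for the others.

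The interaction with age asks whether the knockout's effect differs between 6 and 18 weeks, and it was called for Rgs12, a regulator of G protein signalling within 25 Mb of Kmt2c on chromosome 5 (ENSMUSG00000029101, 34949445 to 35039644), at 0.63 (SE 0.10, adjusted p = 0.00548). Its knockout fold changes were -0.01 and -0.15 in 6-week males and females and 0.54 and 0.57 in 18-week males and females. Clock genes had a lower knockout effect at 18 than at 6 weeks (adjusted p = 2.53e-05; adjusted p = 0.00861 with an estimated correlation). The clock list was planned as a check of composition and handling. Its median was below 0 in 18-week males alone (-0.116), with 0.001 and 0.048 in 18-week females of batches 1 and 2. At 6 weeks it was 0.08 in males and 0.088 and 0.105 in females of batches 1 and 2. Of 18 clock genes, edgeR called 0 over all genes and 4 were lower adjusted over the list alone, among them Hlf (-0.27, SE 0.07) and Nr1d2 (-0.19). Synaptic adhesion genes did as well, with 0 of 60 called by edgeR over all genes or adjusted over the list alone (adjusted p = 9.65e-05; adjusted p = 0.83 with an estimated correlation), and with the gene length trend removed this call ended (adjusted p = 0.271). For the interaction with sex edgeR called 0 genes, with 1740 at an unadjusted p under 0.05 and 17 called by DESeq2, so an effect called in 1 sex and not in the other is not shown to differ. Immediate early genes had a higher knockout effect in females (adjusted p = 4.85e-05; adjusted p = 0.879 with an estimated correlation), with 0 of 26 called over all genes and 2 higher adjusted over the list alone. Without the 6-week females of batch 1 the interaction with age gave 0 genes by edgeR.

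Age in wild types asks how these neurons change between 6 and 18 weeks. Tnc, the extracellular matrix gene tenascin C, fell by 2.21 on the log2 scale (SE 0.18, n = 9 and 10, edgeR adjusted p = 6.78e-12). Rab37, a vesicle GTPase gene, rose by 1.49 (SE 0.17, adjusted p = 3.27e-08). Ass1, an enzyme of arginine synthesis (1.07, SE 0.13, adjusted p = 1.11e-07), and the matrix gene Fbln2 (1.03, SE 0.13, adjusted p = 1.15e-06) rose too. Both ages shared a run folder in the females of batch 2 only, and there these 4 also passed, at -1.12, 1.03, 1.28 and 1.53. In the same libraries the mean score of other cell types fell, from between 0.667 and 1.19 to between -0.148 and 0.108. Age was therefore not separated there from a change in the share of other cells. Marcksl1 (-1.68, SE 0.15) and Sox6, a transcription factor of interneurons and glia (-1.65, SE 0.17), fell. Both passed within batch 2 but not within batch 1, where Sox6 had 0.42. Col6a4 (1.39), Trim7 (1.19), Ano2 (1.01), Evc (1.00) and Ttc39a (0.98) were called higher over all wild types but did not pass within batch 2. The mitochondrial transcripts mt-Nd2, mt-Nd5, mt-Rnr1, mt-Nd4 and mt-Nd1 (-2.42, -2.17, -1.98, -1.98 and -1.59) and the structural RNAs Rn7s1 and Rn7s2 (-2.77 and -1.76) fell in the fit of all wild types. In males, whose ages were in different runs, they had between -5.94 and -3.62. None of these 7 fell past the threshold within either batch of females, and Rn7s2 rose in batch 1 (3.11, adjusted p = 0.0257). In batch 2 mt-Nd1 had 0.25 and the others between -0.63 and -0.26 (adjusted p from 0.504 to 0.779), so a fall with age is not shown for them.

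Potassium channel genes rose with age (19 of 38 over all genes with 1 lower, and 20 with 1 lower adjusted over the list alone; adjusted p = 6.67e-07; adjusted p = 0.0491 with an estimated correlation), with Kcnc1 at 0.36 (SE 0.04). Ribosomal protein genes fell over all wild types (63 of 75 lower, 67 adjusted over the list alone; adjusted p = 4.65e-29; adjusted p = 0.0491 with an estimated correlation). Mitochondrially encoded genes did as well (10 of 12 lower, also adjusted over the list alone; adjusted p = 1.25e-14; adjusted p = 0.0491 with an estimated correlation). Within the females of batch 2 these 3 lists were not called (adjusted p = 0.167, 0.102 and 0.614). There, by contrast, markers of other cells were lower at 18 weeks, by a median log2 of -1.129 for astrocytes (adjusted p = 0.00456 with an estimated correlation), -0.901 for inhibitory neurons (0.00877), -0.811 for oligodendrocytes (0.00877), -1.095 for their precursors (0.0203) and -1.455 for microglia (0.00877). In wild-type females of batch 1, whose ages were in different runs, the mean score of other cell types instead rose, from between -0.589 and -0.407 to between 0.039 and 0.575, so a fall with age is not shown for these markers either. The test called 4274 genes, 2052 higher and 2222 lower, 338 of them at 2-fold or more. The females of batch 2 gave 1606 calls, 819 of them among the 4274, the females of batch 1 4999 (1608 among them), and males, whose ages were in different runs, 5544.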

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

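The tests of a linked strain variant, of handling stress and of other cell types, the fits with the length trend removed or a covariate added, and the splits of females with all other labels kept, were chosen after the results they concern were seen.

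Genes near Kmt2c on chromosome 5 were called more often than elsewhere. Within 25 Mb, with Kmt2c, Evc and Evc2 left out, 24 of 269 genes passed (8.92%), a share above that of 99.2% of 15013 windows of the same width on other chromosomes, which overlap one another and reach 10.78% at most. This is what a strain variant carried along with the targeted allele would give, so it may account for part of the fall of Evc, Evc2, Fam126a and Ldb2 and of the values of Insig1 and Rgs12, which lie in the window. The sample titles do not say whether the wild types also carry the targeted allele, in which case such a variant need not differ between genotypes. An effect of the lost Kmt2c on these neighbours was not tested and stays open, because a linked variant would travel with the allele. Oprk1, Cpa6 and B3gat2 lie outside the region but near one another, between 5588466 and 23849158 on chromosome 1. The share of calls around these 3 genes was not tested, so a linked variant is not excluded for them.

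Immediate early genes and sterol synthesis genes were called higher in the average, with 5 of 26 and 5 of 24 members passing over all genes. Neither list call held with an estimated correlation (adjusted p = 0.563 and 0.28), which was not run with the covariate below. The list median was above 0 in 6 of 6 run sets for either list, which argues against a rise confined to 1 run or a few libraries. These sets also make up the average that called the lists, so they are not independent of it. Ribosomal protein genes and layer 6 and subplate markers were above 0 in 6 of 6 sets as well. The early gene median was 0.058 in 18-week males. Markers of other cell types, which the sort should remove, had means above 0 over the run sets in 6 of 6 lists, but by more than 2 SE for inhibitory neurons alone (0.115, SE 0.046). Mbp, a myelin gene at an average log2 CPM of 7.39, had -0.182 (SE 0.061, adjusted p = 0.0812), while with batch 1 alone astrocyte markers were called higher (adjusted p = 0.0457). The astrocyte list includes Slc1a2 and Rorb, abundant here at an average log2 CPM of 10.22 and 8.18, and Rorb itself was called higher in the average. The precursor list includes Tnr at 9.68. Such members need not come from other cells, so the lists and their score need not measure those cells alone. A larger share of other cell types is therefore neither shown nor excluded. With the score of other cell types as a covariate camera still called the early and sterol gene lists (adjusted p = 7.73e-06 for early genes and 4.43e-09 for sterol genes). As far as the score measures a larger share of other cells, this argues against that share as the whole cause, not as a part of it. Handling stress of the nuclei stays open, with the heat shock and dissociation stress list at an adjusted p = 0.0578, as does an effect of the knockout itself.

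In 18-week males more genes were called than in the other combinations of age and sex, and synaptic adhesion genes were called lower, with 9 of 60 members passing over all genes. That list call did not hold with an estimated correlation (adjusted p = 0.514). The order of the counts depends on processing: 6-week and 18-week females gave 288 and 175 against 94 with the length trend removed, and 50 and 247 against 25 with surrogate variables. In 18-week females it was 75 against 55 in separate fits and 17 against 3 without batch terms. Removing a trend over gene length took the count from 402 to 94 and the median of the adhesion list, whose members are mostly long, from -0.122 to 0.052 (adjusted p = 8.95e-05 and 0.28), as a gene length bias between these libraries would. A single library standing apart is not excluded either, since the count fell to 21 without knockout replicate 1. The loss of the adhesion call is consistent with a technical length trend, but a knockout effect on long genes would be removed by the same correction, and that stays open. So does a larger share of other cell types, whose score was -0.575 ± 0.097 in knockouts and -0.715 ± 0.195 in wild types (mean and SD), with 6 of 6 list medians above 0. Expression of Oprk1, Drd1, Cpa6 and Olfr78 passed with the trend removed.

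Other splits of the same libraries gave counts as large as the real one rarely for some comparisons and more often for others. For the average 1 of 100 splits, the real one, gave as many as 799 calls, and the highest other gave 1. For 18-week females it was 1 of 100 (96 calls, highest other 53) with all other labels kept, or 1 of 100 with the other groups split as well (highest other 2), and for 18-week males 1 of 35 (402 calls, highest other 147), or 1 of 100 with the other groups split as well (highest other 309). For 18-week males 1 of 35 is the smallest share possible. For the interaction with age it was 1 of 100 (1 gene, highest other 0) and for age in wild types 1 of 50 (4274 calls, highest other 2854). Age labels were permuted within sex, and age went with run in males and in females of batch 1. The splits therefore do not tell age from run. In 6-week females 6 of 100 splits gave as many as 74 with all other labels kept, and the highest other gave 654, so chance cannot be excluded for the count. With the other groups split as well it was 2 of 100 (highest other 222), but there the real labels of 6-week females gave 25. The other 5 splits with all other labels kept leave batch 1 as labelled, which alone gave 1318 calls, and shuffle batch 2, which alone gave 2. Why splits that shuffle batch 2 can give counts several times the real one was not tested. Exchanging wild-type and knockout replicates 4 gave 390. Of the 10 genes that separate the genotypes best without these 2 libraries, 9 differed between the 2 in the direction of their labels. Among them was Cpa6, at 16.7 CPM in the wild type and 7.96 CPM in the knockout. For some of the 10 wild-type replicate 4 lay nearer the other knockouts of its batch than the other wild types. It had 33.6 CPM of Palmd (means 30.9 and 40.1) and 52.4 CPM of Ccdc88c (53.3 and 68.9). In 6-week males 2 of 35 splits, or 8 of 100 with the other groups split as well, gave as many as 1 call (highest other 1), so chance cannot be excluded for the count. For the interaction with sex the real count is 0, which any split reaches (100 of 100, highest other 5), so the splits decide nothing there.

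The interactions tested differences between groups. Rgs12 had a different knockout effect by age (adjusted p = 0.00548), as did the list of clock genes (adjusted p = 2.53e-05; adjusted p = 0.00861 with an estimated correlation). The clock list median was above 0 in 5 of 6 run sets and was -0.116 in 18-week males. Synaptic adhesion genes were called by age (adjusted p = 9.65e-05), but not with an estimated correlation (adjusted p = 0.83). By sex immediate early genes had a higher knockout effect in females (adjusted p = 4.85e-05), but not with an estimated correlation (adjusted p = 0.879). So did synaptic adhesion genes (adjusted p = 2.92e-04; adjusted p = 0.879 with an estimated correlation; median 0.096). Neuropeptides and secreted signals did as well (adjusted p = 0.0316; adjusted p = 0.873 with an estimated correlation; median 0.118). For both of these edgeR called 0 members, over all genes or adjusted over the list alone. With the gene length trend removed the adhesion calls ended, as the medians went from -0.071 to -0.02 by age (adjusted p = 0.271) and from 0.096 to 0.022 by sex (adjusted p = 0.438).

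Single libraries stood far from the others of their group in 5 of 59 tested combinations of a measured value and a group. Chance gives about 1 in 20 per combination, but the combinations share libraries and pool both batches of females, so they are not independent. Wild-type 6-week males, with 3 libraries, were not tested. The long gene balance of wild-type 6-week female replicate 6 was 0.479, the others lying between 0.004 and 0.172. Ccn1 was at 7.76 CPM in knockout 6-week female replicate 2 (others 12.9 to 14.9), and Oprk1 at 9.03 CPM in knockout 18-week male replicate 3 (others 10.2 to 10.4). B3gat2 was at 12.8 CPM in knockout 6-week male replicate 3 (others 9.15 to 9.48). Evc was at 3.32 CPM in knockout 18-week female replicate 4 (others 0.958 to 1.64), within the range of the wild types of its batch (2.94 to 5.06). Its Cpa6 (7.02 CPM) and Oprk1 (10.8 CPM) lay with the knockouts of that batch, where wild types had 12.6 to 16.3 and 4.82 to 7.88 CPM.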

How the results depend on the processing

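Gene length removal, the sets without 6-week females of batch 1, the covariate for other cell types and the age lists within batch 2 were chosen after the data were seen. Counts are given in the order 6-week males, 6-week females, 18-week males, 18-week females, average, interaction with age, interaction with sex and age in wild types, and were 1, 74, 402, 96, 799, 1, 0 and 4274. DESeq2 gave 3, 421, 834, 244, 1204, 2, 17 and 4471, and no filter on low counts 101, 769, 1241, 594, 1591, 97, 235 and 4161. RLE scaling gave 118 in 6-week females and otherwise counts within 1.5 times, as did removal of small and mitochondrial RNAs throughout. Without batch terms the counts were 0, 3, 3, 17, 162, 0, 0 and 2415. The replicate block gave 0, 16, 145, 59, 486, 1, 0 and 626, although same-number samples do not resemble each other. Of 19 pairs 4 had a residual correlation over 0.1, and in 3 the wild type correlated best with the knockout of its own number. With 2 surrogate variables the counts were 5, 50, 25, 247, 357, 1, 1 and 3686. Separate fits gave 30, 47, 55 and 75, batch 1 alone 1318 in 6-week and 23 in 18-week females, and batch 2 alone 2 and 0. Age gave 5544 in males, 2567 in females, 4999 in batch 1 and 1606 in batch 2. With the gene length trend removed counts were 1, 288, 94, 175, 690, 1, 0 and 4392, of which 74, 77, 95 and 530 were shared for 6-week females to the average. Higher and lower calls in 18-week males, 116 and 286, became 40 and 54 with that trend removed and 650 and 591 with no filter. Without the 6-week females of batch 1 the average gave 309 calls and the interactions 0 and 2, and with the covariate for other cell types the average gave 478, of which 460 were shared. The cause of these shifts was not tested, except that separate fits and single batches use fewer samples. Males have no batch term, so without batch terms their counts moved only through the spread per gene that all groups share.

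With each library left out in turn the counts ran from 0 to 0 in 6-week males, 10 to 308 in 6-week females, 21 to 787 in 18-week males, 44 to 158 in 18-week females, 493 to 1227 in the average, 1 to 4 and 0 to 0 in the interactions and 3364 to 4446 with age. The average moved by over 1.5 times without knockout 18-week male replicate 1 (506), wild-type 6-week male replicates 1 (494) and 3 (493) and wild-type 6-week female replicate 4 (1227). The interaction with age gave 4 without wild-type 18-week male replicate 1 and 3 without wild-type 18-week female replicate 5. It gave 2 without knockout 18-week female replicate 5, wild-type 6-week male replicate 3, wild-type 6-week female replicate 4 or knockout 6-week female replicates 3 or 4.

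Lists called numbered 2, 16, 12, 5, 10, 2, 3 and 17 by camera, 0, 0, 0, 1, 0, 1, 0 and 3 with an estimated correlation and 0, 0, 3, 2, 4, 1, 0 and 24 by fry. The age lists within batch 2 numbered 9, and the average gave 10 with batch 1 alone and 7 with the covariate. Batch 1 alone called astrocyte markers (adjusted p = 0.0457) and mitochondrially encoded genes (adjusted p = 0.00323) but not axon guidance or oxidative phosphorylation genes (adjusted p = 0.066 each). The covariate ended the calls of ribosomal protein, histone and oxidative phosphorylation genes (adjusted p = 0.161, 0.148 and 0.191). Correlations of fold changes between combinations rose to between 0.139 and 0.393 among genes with a log2 CPM of at least 3 (0.275, 0.322, 0.149). With a library left out the long gene balance ran from -0.104 to -0.006 in 6-week males, -0.058 to 0.038 in 6-week females, -0.283 to -0.169 in 18-week males and -0.108 to 0.05 in 18-week females. The sign reversed in 6-week females without wild-type replicate 6 (0.038) or knockout replicate 3 (0.002), and in 18-week females without wild-type replicates 4 (0.031), 5 (0.001) and 6 (0.029) or knockout replicate 1 (0.05). The 18-week male difference had exact p = 0.0857 without wild-type replicate 1 or 2, 0.0571 without wild-type replicate 3 or 4 and 0.0286, the smallest that 35 splits allow, without any 1 of the knockouts.

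Among the 102 values for named genes, those of Cpa6 in 6-week females, Oprk1 and Olfr78 in 18-week males, Tnc, Rab37, Ass1 and Fbln2 with age and, in the average, Oprk1, B3gat2, BB557941, Cntnap3, Evc, Cpa6, Evc2, Olfr78, Cxcl12, Pde3a, Kirrel, Chst9 and Kcnk13 passed under each alternative run for them (11, 9, 12 and 9 per gene) and with each library left out. These 13 genes of the average also passed with the covariate for other cell types, where Btg2, Nek3, Vwa5a and Kdm5d did not (adjusted p = 0.058, 0.0591, 0.058 and 0.0609). Calls were lost for 1 value under DESeq2, 57 without batch terms, 40 with the replicate block, 26 with surrogate variables and 10 with the length trend removed, and for 223 of 1846 values with 1 library left out. With fewer libraries they were lost for 21 of 61 values in separate fits, 18 of 40 with batch 1 alone, 38 of 40 with batch 2 alone and 6 of 21 without the 6-week females of batch 1. Of 20 values with age they were lost, reversals apart, for 1 in males, 7 in females, 5 in females of batch 1 and 10 in females of batch 2. Rgs12 was lost without batch terms and without the 6-week females of batch 1. Reversed values were all in age: Col6a4 -0.37, Rn7s1 2.1, mt-Rnr1 0.19, mt-Nd4 0.18, Rn7s2 3.11, Sox6 0.42 and mt-Nd1 0.67 in females of batch 1, Ttc39a -0.11 and mt-Nd1 0.25 in batch 2, and Rn7s1 0.73, Rn7s2 1.25 and mt-Nd1 0.46 in all females. On simulated data edgeR found 6%, 28%, 18% and 22% of genes changed by a log2 of 0.25 in the 4 combinations and 74% in the average, so small changes within 1 combination are mostly below reach.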

Other observations

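The tests of knockout effects against the age difference were planned, and the genes named in this part were chosen after their values were seen.

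Other genes also moved in the average. The opioid peptide genes went opposite ways: Pdyn, the precursor of dynorphin, the ligand of the kappa opioid receptor, fell by 0.53 (SE 0.10, edgeR adjusted p = 3.74e-04), while Penk, the precursor of enkephalins, rose by 0.40 (SE 0.11, adjusted p = 0.0367). Among clock genes Arntl (-0.17, SE 0.03, adjusted p = 0.00175) and Npas2 (-0.17, SE 0.03, adjusted p = 0.0019) fell, and Dbp (0.16, SE 0.05, adjusted p = 0.0476) and Rorb (0.30, SE 0.06, adjusted p = 0.00338) rose. Among GABA receptor subunit genes Gabra5 (-0.21, SE 0.03, adjusted p = 6.46e-05) and Gabrb1 (-0.13, SE 0.03, adjusted p = 0.00857) fell. Of 60 synaptic adhesion genes 6 rose and 6 fell over all genes, and 10 rose and 15 fell adjusted over the list alone, and the list was not called (adjusted p = 0.17). With the gene length trend removed it was called higher (adjusted p = 1.52e-04; adjusted p = 0.484 with an estimated correlation), so its direction depends on that trend. Cadm1 fell (-0.26, SE 0.04, adjusted p = 4.27e-06), and Cdh9 rose (0.27, SE 0.07, adjusted p = 0.0224). Of 57 autism risk genes 2 rose and 1 fell, namely Rorb, Nlgn3 (0.23, SE 0.07) and Shank2, and the list was not called (adjusted p = 0.122).

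Slc17a6, a glutamate transporter gene of subcortical neurons and of young cortical neurons, rose by 0.28 (SE 0.06, edgeR adjusted p = 0.00164). The calcium channel genes Cacna1h (-0.22, SE 0.05, adjusted p = 0.00299) and Cacna2d3 (-0.21, SE 0.05, adjusted p = 0.00527) fell. Among potassium channel genes Kcnab1 (-0.20, SE 0.04, adjusted p = 0.00119) and Kcnc2 (-0.20, SE 0.04, adjusted p = 0.00229) fell, and Kcnh5 (0.18, SE 0.04, adjusted p = 0.00295) and Kcnv1 (0.21, SE 0.05, adjusted p = 0.0132) rose.

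A hypothesis was that the knockout runs along or against the change with age. Knockout effects in males correlated across genes with the wild-type age difference in females at a Spearman rho of 0.207, and 13 of 100 permuted splits gave one as large in size (highest other 0.294). For knockout effects in females and the age difference in males rho was -0.143, and 45 of 100 splits gave one as large (highest other 0.367). Neither differed from other splits, and the signs were opposite.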
